A study of Mus musculus with 9 samples.

How the data were processed

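Gene expression was measured in 9 samples of mouse macrophages on Agilent single-colour arrays with Cy3-labelled RNA. Per the labels, the samples form 3 groups of 3: macrophages of the peritoneal exudate (PECs), used as controls, and tumour-associated macrophages (TAMs) of a fibrosarcoma, divided into an F4/80high and an F4/80low subset. All came from C57BL/6J mice, and total RNA was extracted with a column kit. The labels name F4/80 as the marker that divides the TAMs and give no other marker of the sort gates. The series calls the samples of a group biological replicates and does not say whether each came from a separate animal, so every p-value measures only the spread between these samples, which may in part be technical.

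The deposited scanner files hold a linear spot intensity from Agilent Feature Extraction, per the file headers, after the software's background subtraction and spatial correction. Each array has 62976 spots, of which 3671 are controls. The deposited value table holds log2 values for 9703 probes, and its column medians lie between 8.26 and 8.35. Its log2 scale was read from the values, which are not centred on 0, and its normalization and the filter that chose its probes are not stated, so it served only as an alternative. Between 36.1% and 38.3% of the 59305 other spots were well above background on each array. No spot was saturated, and between 103 and 307 spots per array carried an outlier mark of the software and were left out. The number of arrays limits the precision: the median standard error of a log2 fold change was 0.236.

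The processed intensity was put on the log2 scale, and each array's 75th percentile over non-control spots was subtracted. Levels below are therefore log2 values relative to that percentile, which corresponded to intensities between 53.5 and 97.3. Spots of the same probe were averaged. Probes took the symbol of the reference table where an accession matched (26413 probes, of which 3093 changed name) and otherwise kept the name in the file (29268 probes). A probe was kept when it was well above background on all 3 arrays of at least 1 group (21196 probes), and the brightest probe stood for its gene. This left 16463 genes, of which 1625 are known only by a chromosome range. Probe positions are those of the files (mouse build mm9); exon annotation was not used here.

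Genes were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with all 9 arrays in a single fit, 3 contrasts and the Benjamini-Hochberg adjustment within each contrast at 0.05. All tests were two-sided. A gene above background on all arrays of one group and on none of the other is given as "at least N-fold". The dimmer group enters at its measured level or, where higher, at the lowest level of any spot well above background on that array. This limit is not specific to the gene's own spot, so the bound is approximate. No fold is given where neither group was above background throughout. The genes named are Adgre1 and Hmox1, the 6 largest rises and the 6 largest falls among genes above background in both groups, the 3 largest bounds in each direction, up to 3 members of each gene list that passed its test, and genes called in opposite directions in the TAM subsets. The largest rises and falls and the genes called in opposite directions had to have no overlap between the arrays of the compared groups. For genes given as bounds this largely followed from the rule. The arrays of the other named genes past the threshold did not overlap either. Chance gives this for 10% of genes with 3 arrays against 3, a share that does not apply to genes chosen for a large change.

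Gene lists for macrophage programmes and for other cell types (31 in all) were tested as sets with limma's camera at a preset correlation of 0.01, adjusted over the 26 lists with at least 5 measured members; the other 5 are given as counts. Members given as bounds enter a list's median at their bound. Camera with an estimated correlation between genes and the fry test were the alternatives. These choices, the comparisons and the rule for named genes were fixed before the data were examined. The lists were written from general knowledge, not from these samples.

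The arrays lie on a pair of slides: slide 1 holds PEC replicate 1 and all 6 TAM arrays, and slide 2 holds PEC replicates 2 and 3. Each PEC comparison was therefore repeated with slide as a block and within slide 1 alone, where the lone PEC array is assumed to vary like the other groups; both give the same fold changes because slide 2 holds no TAM array. The comparison between TAM subsets lies within slide 1. Replicate numbers were checked for pairing by the correlation of residuals across genes, which are not independent replicates: F4/80high and F4/80low arrays of the same number gave 0.23, 0.17 and 0.13, and arrays of different numbers gave at most 0.02, so a replicate block was run beside the unpaired fit. Other alternatives were normexp background correction, quantile normalization, median centring, no filter on dim probes, a stricter one, outlier spots kept, mean over probes, each probe tested, an intensity trend with robust moderation, a fold minimum of 2, only the groups compared, the deposited value table and leaving out each array. Added after the data were seen were the 75th percentile over spots above background on all 9 arrays, slide 1 alone, the replicate block on TAM arrays alone and the removal of a dim patch of 1 array.

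The fit was tested on simulated data with 100 genes shifted by each fold among 16450. It recovered 30%, 31% and 18% of 2-fold changes in the F4/80high against PEC, F4/80low against PEC and F4/80high against F4/80low comparisons, and 94%, 88% and 87% of 4-fold changes. It called 11 of 16228 unshifted genes in the comparison of F4/80high TAMs with PECs, and 5 and 6 of 16227 in the others. Far fewer genes were shifted than the 8737, 8541 and 5369 called in the real comparisons. The adjusted threshold was therefore stricter in the simulation, and the recovered shares are not those of the real data.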

Results

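Messenger RNA was profiled in 9 samples of C57BL/6J mouse macrophages: 3 of PECs, 3 of F4/80high TAMs and 3 of F4/80low TAMs from a fibrosarcoma. On each array between 21421 and 22695 of 59305 non-control spots were well above background, and 16463 genes were tested. The series sets TAMs against PECs, and its comparisons ask how macrophages in a tumour differ from macrophages of the peritoneal cavity, and how the TAM subsets differ from each other. Tumour and tissue of origin differ together between TAMs and PECs, and the handling of the cells may differ too. Their effects cannot be told apart here. Levels are given as mean ± SD on the log2 scale, relative to each array's 75th percentile, with n = 3 arrays per group.

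The macrophages separated by origin and then by F4/80 level. The first principal component held 59.0% of the variance and parted the PECs from the TAMs, and the next held 26.2% and parted F4/80high from F4/80low TAMs. Correlation between arrays, across genes that are not independent replicates, was 0.979 to 0.992 among PECs, 0.977 to 0.989 among F4/80high TAMs and 0.964 to 0.979 among F4/80low TAMs. Arrays of different TAM subsets correlated at 0.889 to 0.921. F4/80high TAMs and PECs correlated at 0.834 to 0.854, and F4/80low TAMs and PECs at 0.847 to 0.869.

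**Figure D1:**
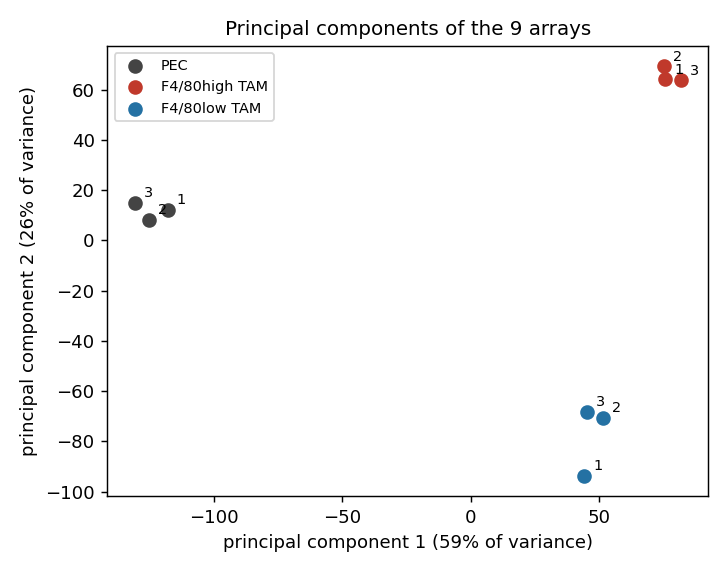
Scores of the 9 arrays on the first and second principal components of the log2 levels, with the percent of variance on each axis and each point an array coloured by group. The first component (59.0% of the variance) parts the 3 PEC arrays from the 6 TAM arrays, and the second (26.2%) parts F4/80high from F4/80low TAMs.

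Adgre1 encodes F4/80, the surface marker that defined the subsets, so its difference between them follows from the sort. Its probe lies on chromosome 17 (mm9, 57622868 to 57622927). Adgre1 reached 5.88 ± 0.25 in PECs, 5.94 ± 0.26 in F4/80high TAMs and 2.89 ± 0.50 in F4/80low TAMs. F4/80high TAMs did not pass the test against PECs (log2 fold change 0.05, SE 0.27, adjusted p 0.882). F4/80low TAMs lay 7.96-fold below PECs (log2 fold change −2.99, SE 0.27, adjusted p 3.37e-05) and 8.26-fold below F4/80high TAMs (adjusted p 8.22e-05).

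Hmox1 encodes heme oxygenase 1, the inducible enzyme that degrades heme. Its probe lies on chromosome 8 (mm9, 77624207 to 77624266). Hmox1 was among the bright transcripts in every group, at 7.40 ± 0.83 in PECs, 8.50 ± 0.09 in F4/80high TAMs and 7.01 ± 2.52 in F4/80low TAMs. None of the comparisons passed the test: the log2 fold change was 1.10 (SE 1.02, adjusted p 0.390) in F4/80high TAMs against PECs, −0.39 (SE 1.02, adjusted p 0.769) in F4/80low TAMs against PECs, and 1.48 (SE 1.02, adjusted p 0.307) between the TAM subsets. The large SD in F4/80low TAMs came from replicate 2, at 4.16 against 7.94 and 8.94 in the other two, and without it the difference from PECs was 1.04 (SE 0.47, adjusted p 0.101) and the difference between subsets 0.06 (SE 0.47, adjusted p 0.944). With F4/80high TAMs and PECs fitted alone, the same 1.10 passed the threshold. With slide as a block the log2 fold changes against PECs were 2.02 and 0.53, neither past the threshold. Its second probe gave 1.08, 0.59 and 0.49 in the same order of comparisons (SE 0.54).

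**Figure D2:**
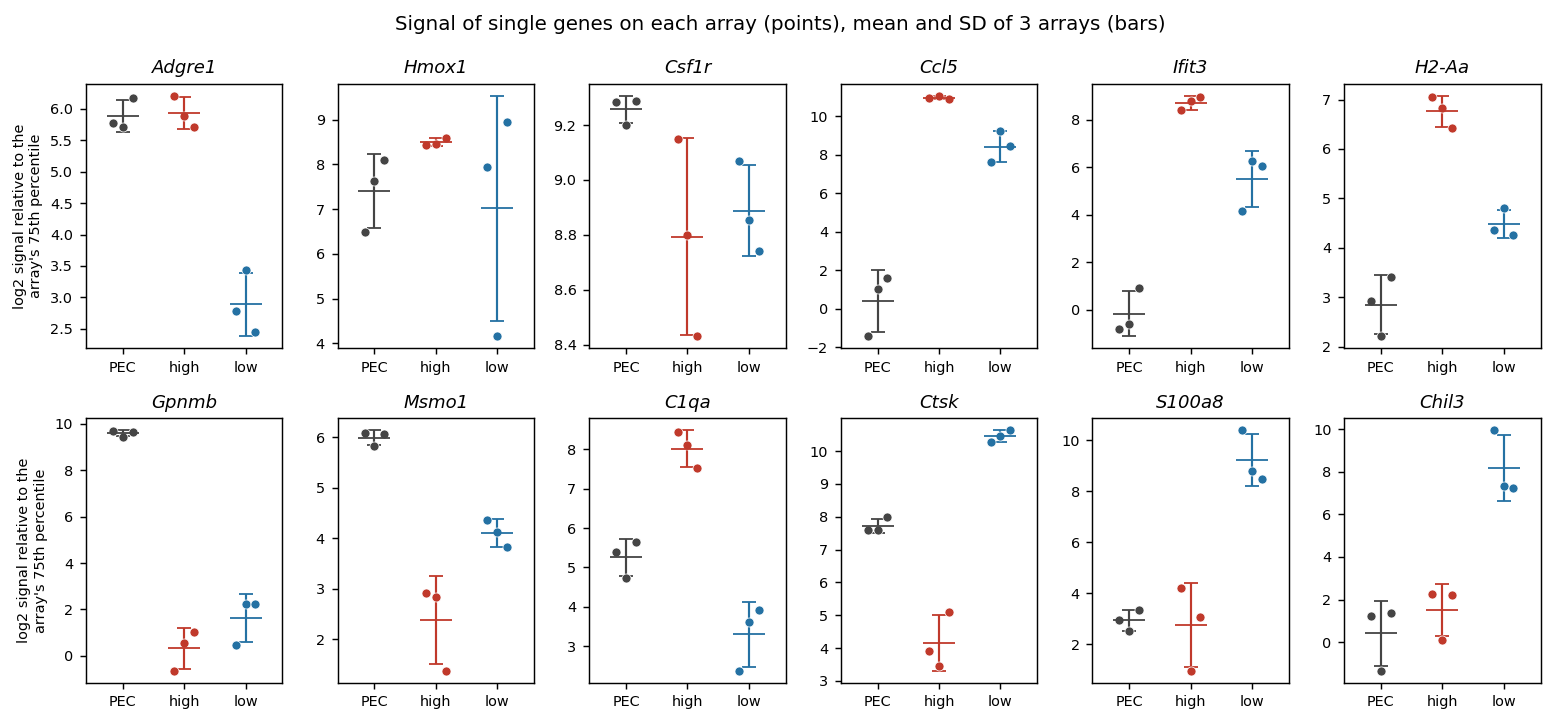
Log2 level relative to each array's 75th percentile for 12 genes in PECs, F4/80high TAMs and F4/80low TAMs, with a point for each array and bars for the mean and SD. Ccl5 and Ifit3 are higher in both TAM subsets than in PECs, Gpnmb is lower in both, and Hmox1 is low in a single F4/80low array, at 4.16.

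F4/80high TAMs, compared with PECs, carried far more transcript of inflammatory cytokines, chemokines and interferon-induced genes, and less of cholesterol synthesis genes and of Gpnmb, Cd36 and Lpl. Ccl5, a chemokine that draws T cells and monocytes, rose by a log2 fold change of 10.58 (SE 0.70, adjusted p 4.24e-06), from 0.40 ± 1.61 in PECs to 10.98 ± 0.09 in F4/80high TAMs (9.67 without PEC replicate 1 and 11.18 without PEC replicate 3). Cxcl10, an interferon-induced chemokine, was at least 5843-fold higher, and Il1b, a cytokine of acute inflammation, at least 488-fold higher. Gpnmb, a glycoprotein of lysosomes and melanosomes, fell by 9.27 (SE 0.53, adjusted p 1.94e-06), and Cd36, a scavenger receptor that takes up oxidised lipoprotein and fatty acids, was at least 866-fold lower. In all, 8737 of 16463 genes passed the limma test, 4120 higher and 4617 lower.

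The other large rises in F4/80high TAMs were in Gbp5, an interferon-induced GTPase that went from −1.92 ± 0.35 to 8.08 ± 0.08, Socs3, a feedback inhibitor of cytokine signalling (log2 fold change 9.20, SE 0.35), Mx1, an antiviral GTPase (8.95, SE 0.57), Acod1, the enzyme that makes itaconate (8.92, SE 0.38), and Ifit3, an antiviral effector (8.90, SE 0.60). Marcksl1 was at least 540-fold higher. The other large falls were in Fabp7, a fatty acid binding protein (−7.61, SE 0.30), the kinase Cdk18 (−7.25, SE 0.28), Lpl, the lipase that frees fatty acids from lipoproteins (−6.77, SE 0.18), Mfge8, a bridge between phagocytes and apoptotic cells (−6.73, SE 0.26), and Mmp12, the macrophage elastase (−6.50, SE 0.54). Npy, which encodes neuropeptide Y, was at least 278-fold lower and Mamdc2 at least 163-fold lower. The Ccl5 probe lies on chromosome 11 (mm9, 83339296 to 83339355) and the Gpnmb probe on chromosome 6 (mm9, 49006386 to 49006445).

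Type I interferon response genes, which encode antiviral sensors and effectors, rose as a set in F4/80high TAMs: 23 of 23 measured members were higher (median log2 fold change 5.52, as for the other lists, adjusted p 4.81e-14 by camera). The interferon list had adjusted p = 0.465 with an estimated correlation and a median of 6.05 within slide 1. Ifit2 rose by 9.07 (SE 0.50) and Ifit1 by 8.91 (SE 0.51), from PECs in which they were above background on 1 and 2 of 3 arrays. Genes of classical inflammatory activation rose in 14 and fell in 1 of 15 (median 6.57, adjusted p 3.9e-09). On all 3 PEC arrays, 9 of 18 inflammatory and 11 of 21 chemokine members listed were above background. On all 3 F4/80high arrays the numbers were 15 and 18. Members kept by the filter on dim probes only through TAMs were bound to rise. The inflammatory list had adjusted p = 0.0291 with an estimated correlation and a median of 6.19 within slide 1. Chemokine genes rose in 14 and fell in 2 of 20 (median 3.13, adjusted p 2.98e-05), among them the monocyte attractant Ccl12, at least 193-fold higher. The chemokine list had adjusted p = 0.380 with an estimated correlation and a median of 3.62 within slide 1. MHC class II genes, which present antigen to helper T cells, rose in 8 and fell in 0 of 10 (median 2.47, adjusted p 0.000376), among them H2-Eb1 (4.39, SE 0.31) and H2-Aa (3.91, SE 0.31). The MHC class II list had adjusted p = 0.471 with an estimated correlation and a median of 2.27 within slide 1.

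Immune checkpoint and suppression genes rose in 7 and fell in 2 of 14 (median 0.84, adjusted p 0.0456), a call lost with normexp correction, without PEC replicate 1 and without F4/80high replicate 1. The checkpoint list had adjusted p = 0.471 with an estimated correlation and a median of 0.90 within slide 1. Il10, an anti-inflammatory cytokine, was at least 63.1-fold higher and Nos2, the inducible nitric oxide synthase, rose by 6.57 (SE 0.44). Cell cycle genes rose in 13 and fell in 0 of 20 (median 2.13, adjusted p 0.00923), a call lost within slide 1 and in the fry test. Above background on all 3 arrays were 13 of 24 listed members in PECs and 20 in F4/80high TAMs, so the filter on dim probes bears on this count. The cell cycle list had adjusted p = 0.687 with an estimated correlation and a median of 1.52 within slide 1. Mki67, a proliferation marker, rose by 5.21 (SE 1.02) and the cyclin Ccnb2 by 4.34 (SE 0.70), each above background on 1 of 3 PEC arrays, and the topoisomerase Top2a was at least 4.27-fold higher. Dissociation and immediate early genes, which respond to tissue handling and stress, rose in 9 and fell in 3 of 14 (median 2.27, adjusted p 0.0376), with the chaperone Hspa1a up by 6.79 (SE 0.34) and Ier3 by 5.46 (SE 0.49); without PEC replicate 1 or F4/80high replicate 1 the call was lost. The dissociation list had adjusted p = 0.471 with an estimated correlation and a median of 1.87 within slide 1. Monocyte markers rose in 7 and fell in 0 of 10 (median 1.50, adjusted p 0.0336), a call lost with normexp correction, within slide 1 and without F4/80high replicate 3. The monocyte list had adjusted p = 0.471 with an estimated correlation and a median of 1.31 within slide 1. Ccr2, the receptor that brings monocytes to tissue (2.94, SE 0.89), and Plac8 (2.81, SE 0.74) were above background on 1 of 3 PEC arrays, and a second Plac8 probe gave 0.43 (SE 0.40). Without PEC replicate 1, Mki67 stood at 6.15, Ccr2 at 4.25 and Plac8 at 2.05. Without PEC replicate 2, Ccr2 stood at 2.30, short of the threshold, and Plac8 at 3.44, and without PEC replicate 3, Ccr2 stood at 2.26, again short of it.

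Cholesterol synthesis genes fell in 17 and rose in 0 of 19 in F4/80high TAMs (median −1.89, adjusted p 7.28e-07). The cholesterol list had adjusted p = 0.380 with an estimated correlation and a median of −2.06 within slide 1. Mvd (−4.00, SE 0.36), Cyp51 (−3.90, SE 0.35) and Dhcr7 (−3.78, SE 0.30), enzymes of that pathway, were above background on 2, 1 and 2 of 3 F4/80high arrays. The programme of large peritoneal macrophages, the resident cells of the cavity, fell in 8 and rose in 0 of 11 (median −1.71, adjusted p 0.00777). Above background on all 3 arrays were 10 of 18 listed members in PECs and 5 in F4/80high TAMs. Members kept by the filter on dim probes only through PECs were bound to fall, so this count and test are partly set by the filter. The peritoneal programme list had adjusted p = 0.471 with an estimated correlation and a median of −0.95 within slide 1. Its member Vsig4, a complement receptor, was at least 54.5-fold lower, and Prg4, a lubricating proteoglycan above background on 1 of 3 F4/80high arrays, stood at −4.80 (SE 0.61), or −5.69 without PEC replicate 1. Oxidative phosphorylation genes fell in 12 and rose in 1 of 23 (median −0.45, adjusted p 0.0149), a call lost with slide as a block and within slide 1. The oxidative phosphorylation list had adjusted p = 0.687 with an estimated correlation and a median of −0.36 within slide 1. Its members Ndufa4 (−2.33, SE 0.19), Ndufb3 (−0.93, SE 0.22) and Ndufs1 (−0.91, SE 0.16) encode mitochondrial proteins of the respiratory chain.

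The remaining lists did not pass the set test in this comparison. Members rose and fell, respectively, in 7 and 5 of 17 for alternative activation, 2 and 9 of 17 for heme and iron handling, 2 and 4 of 15 for Nrf2 targets, 2 and 3 of 16 for glycolysis, 5 and 3 of 16 for hypoxia, 6 and 10 of 19 for matrix remodelling, 5 and 9 of 17 for complement and lipid-associated genes, 5 and 6 of 16 for phagocytic receptors and 3 and 4 of 14 for macrophage identity. The complement list passed with slide as a block (median −0.83 before members are put at their bound). For other cells the counts were 4 and 1 of 12 for neutrophils, 3 and 1 of 7 for dendritic cells, 2 and 3 of 11 for T cells, 1 and 0 of 6 for NK cells, 4 and 1 of 5 for mast cells and eosinophils (past the threshold with median centring), and 2 and 2 of 7 for fibroblasts. In lists too small for the test the counts were 0 and 0 of 1 for B cells, 1 and 1 of 3 for endothelium, 0 and 0 of 1 for mesothelium, 1 and 0 of 1 for erythroid cells and 0 and 0 of 1 for platelets. Adjusted over the list alone, the counts differed for heme (2 and 10), complement (6 and 9), checkpoint (8 and 2), neutrophils (3 and 1), NK cells (0 and 0) and endothelium (2 and 1). Median and mean, or either and the test where there was one, differed in sign for the hypoxia, identity, fibroblast and endothelial lists, and for the T cell list only before members are put at their bound.

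PEC replicate 1 shares a slide with the TAM arrays and the other two PEC arrays do not: with slide as a block 5632 genes passed, and of 46 named genes 41 kept their side of the threshold and 0 changed sign. Mki67 (3.34), Top2a, Ccr2 (0.32), Ndufb3 and C1qb (1.57) no longer passed, nor did Ndufs1 within slide 1. In that fit the log2 fold change was 12.41 for Ccl5, 9.87 for Acod1, 9.56 for Ifit3, 9.55 for Mx1, 6.24 for Ier3, 5.86 for Nos2, 4.32 for Plac8, 3.45 for Ccnb2, −3.01 for Prg4 and −5.62 for Mmp12. Plac8 did not pass with normexp correction or in the deposited value table, Top2a did not pass with normexp correction or without PEC replicate 1, PEC replicate 3 or F4/80high replicate 1, and Ccr2 did not pass without PEC replicate 2, PEC replicate 3, F4/80high replicate 1 or F4/80high replicate 2; neither Top2a nor Ccr2 passed without the filter on dim probes.

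F4/80low TAMs, compared with PECs, also carried more inflammatory and interferon-induced transcript, carried less transcript of complement and lipid-associated genes, and in addition carried neutrophil, T cell and NK cell transcripts. S100a9, a calcium-binding protein abundant in neutrophils and monocytes, was 10.70 ± 0.63 in F4/80low TAMs and −2.28 ± 2.19 in PECs, where it was above background on 2 of 3 arrays (log2 fold change 12.98, SE 1.17, adjusted p 3.28e-05; 11.76 without PEC replicate 1 and 13.86 without PEC replicate 3). Cxcl10 was at least 1532-fold higher, Il1b at least 492-fold higher and the neutrophil gene Retnlg at least 468-fold higher (262-fold without F4/80low replicate 1). Gpnmb fell by 7.94 (SE 0.53, adjusted p 6.37e-06), or by 7.35 without F4/80low replicate 1, and Cd36 was at least 781-fold lower. In all, 8541 of 16463 genes passed the limma test, 3741 higher and 4800 lower.

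The other large rises in F4/80low TAMs were in Lcn2, an iron-siderophore binding protein of neutrophil granules (log2 fold change 8.67, SE 1.02), Ccl5 (8.03, SE 0.70), Chil3, a chitinase-like protein of activated macrophages and neutrophils (7.75, SE 0.96), Acod1 (7.51, SE 0.38), Gbp5 (7.16, SE 0.29) and the interferon-induced GTPase Tgtp2 (6.51, SE 0.52). The other large falls were in coagulation factor F7 (−6.29, SE 0.25), the intermediate filament gene Nes (−6.08, SE 0.30), the myelin gene Pmp22 (−5.77, SE 0.62), the retinol pathway enzyme Dhrs3 (−5.67, SE 0.36) and the ubiquitin ligase Rnf128 (−5.60, SE 0.36). Mamdc2 was at least 153-fold lower and Retnla, a marker of alternatively activated macrophages, at least 76.5-fold lower. F4/80low replicate 1 had the highest Lcn2, at 10.21 against 6.36 and 5.40, and without it Lcn2 stood at 7.23, Chil3 at 6.87 and Pmp22 at −5.06. Without F4/80low replicate 3, Lcn2 stood at 9.64 and Pmp22 at −6.38. Ccl5 stood at 7.12 without PEC replicate 1 and 8.63 without PEC replicate 3, and Chil3 at 6.87 without PEC replicate 2. A second probe gave 3.22 (SE 0.41) for Tgtp2 and −3.26 (SE 0.39) for Pmp22.

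Markers of several other cell types rose in F4/80low TAMs. A marker kept by the filter on dim probes only through its level in F4/80low TAMs was bound to be higher there. The counts, medians and set tests of these lists are therefore partly set by the filter. Above background on all 3 F4/80low arrays were 6 of 10 listed NK, 11 of 12 T cell and 4 of 15 mast cell and eosinophil members. On all 3 PEC arrays the numbers were 2, 5 and 1. Neutrophil markers rose in 10 and fell in 0 of 12 (median 6.94, adjusted p 3.92e-05), and 12 of 12 were above background on all 3 F4/80low arrays against 5 in PECs. The neutrophil list had adjusted p = 0.259 with an estimated correlation and a median of 6.60 within slide 1. Its median before members are put at their bound was 7.25, and 5.90 without F4/80low replicate 1 or 8.91 without F4/80low replicate 3. T cell markers rose in 9 and fell in 0 of 11 (median 3.21, adjusted p 1.14e-05), with the receptor chain Cd3d at least 16.8-fold higher. The T cell list had adjusted p = 0.242 with an estimated correlation and a median of 3.06 within slide 1. NK cell markers rose in 6 of 6 (median 3.12, adjusted p 0.000113), with the granzymes Gzma at least 64.7-fold and Gzmb at least 44.5-fold higher. The NK cell list had adjusted p = 0.223 with an estimated correlation and a median of 2.96 within slide 1. Monocyte markers rose in 10 of 10 (median 3.10, adjusted p 1.14e-05), with Plac8 up by 8.54 (SE 0.74; above background on 1 of 3 PEC arrays), by 7.78 without PEC replicate 1 and by 9.17 without PEC replicate 2. The monocyte list had adjusted p = 0.126 with an estimated correlation and a median of 2.43 within slide 1. A second Plac8 probe gave 5.85 (SE 0.40). Mast cell and eosinophil markers rose in 4 and fell in 1 of 5 (median 3.31, adjusted p 0.0130), with Hdc, the enzyme that makes histamine, at least 183-fold (108-fold without F4/80low replicate 1) and the receptor Kit at least 9.91-fold higher. The mast cell list had adjusted p = 0.242 with an estimated correlation and a median of 3.15 within slide 1. Dendritic cell markers rose in 4 and fell in 1 of 7 (median 1.06, adjusted p 0.0300), a call lost with quantile normalization, with the percentile over spots above background on all arrays and without F4/80low replicate 2. The dendritic cell list had adjusted p = 0.259 with an estimated correlation and a median of 0.99 within slide 1. Ccr7, which guides dendritic cells to lymph nodes, rose by 7.24 (SE 0.72; above background on 2 of 3 PEC arrays), or by 6.25 without PEC replicate 1, and the growth factor receptor Flt3 was at least 10.9-fold higher (7.15-fold without F4/80low replicate 2).

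Beside these markers of other cells, inflammatory genes rose in 13 and fell in 1 of 15 (median 4.28, adjusted p 4.68e-08). On all 3 PEC arrays, 9 of 18 inflammatory, 11 of 21 chemokine and 13 of 24 cell cycle members listed were above background. On all 3 F4/80low arrays the numbers were 15, 17 and 19. Members kept by the filter on dim probes only through TAMs were bound to rise. The inflammatory list had adjusted p = 0.0407 with an estimated correlation and a median of 4.24 within slide 1. Type I interferon response genes rose in 21 and fell in 0 of 23 (median 2.89, adjusted p 3.55e-10), with Ifit1 (6.00, SE 0.51; above background on 2 of 3 PEC arrays), Mx1 (5.91, SE 0.57) and Ifit3 (5.67, SE 0.60), the last 2 at 6.58 and 6.34 without F4/80low replicate 1. The interferon list had adjusted p = 0.259 with an estimated correlation and a median of 3.43 within slide 1. Chemokines rose in 11 and fell in 3 of 20 (median 1.03, adjusted p 0.00582), with the neutrophil attractant Cxcl1 at least 31.8-fold higher. The chemokine list had adjusted p = 0.259 with an estimated correlation and a median of 1.10 within slide 1. MHC class II genes rose in 6 and fell in 1 of 10 (median 1.27, adjusted p 0.0156), among them H2-Oa, at least 7.35-fold higher, and H2-Ob, at least 3.68-fold higher, chains of H2-O, which is known from B cells and dendritic cells. The MHC class II list had adjusted p = 0.427 with an estimated correlation and a median of 1.32 within slide 1. Cell cycle genes rose in 11 and fell in 1 of 20 (median 2.11, adjusted p 0.00513), a call lost in the fry test, with Mki67 (4.73, SE 1.02), Ccnb2 (4.49, SE 0.70) and Ccna2 (3.81, SE 1.01) each above background on 1 of 3 PEC arrays. The cell cycle list had adjusted p = 0.565 with an estimated correlation and a median of 1.32 within slide 1. F4/80low replicate 1 had the highest Mki67, at 5.05 against 2.25 and 1.31, and without it the median was 1.25, with Mki67 at 3.64, Ccnb2 at 3.63 and Ccna2 at 2.69. Mki67 and Ccna2 stood at 5.51 and 4.62 without F4/80low replicate 3, and at 5.67 and 4.71 without PEC replicate 1. Dissociation and immediate early genes rose in 9 and fell in 1 of 14 (median 1.43, adjusted p 0.000765), with Hspa1a up by 6.28 (SE 0.34) and the transcription factor Egr1 at least 35.0-fold higher. The dissociation list had adjusted p = 0.242 with an estimated correlation and a median of 1.44 within slide 1.

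Complement, phagocytic receptor, macrophage identity, peritoneal programme, cholesterol synthesis and matrix lists fell in F4/80low TAMs. Complement and lipid-associated genes fell in 16 and rose in 1 of 17 (median −2.35, adjusted p 1.78e-06), with Lpl at −5.04 (SE 0.18). The complement list had adjusted p = 0.242 with an estimated correlation and a median of −2.44 within slide 1. Phagocytic and scavenger receptors fell in 10 and rose in 3 of 16 (median −1.96, adjusted p 0.00513), with Mertk, a receptor for apoptotic cells, at least 20.7-fold lower and the scavenger receptor Marco at −6.49 (SE 0.57; above background on 1 of 3 F4/80low arrays). The phagocytic list had adjusted p = 0.259 with an estimated correlation and a median of −1.79 within slide 1. Macrophage identity genes fell in 7 and rose in 1 of 14 (median −0.77, adjusted p 0.0130). The identity list had adjusted p = 0.297 with an estimated correlation and a median of −1.31 within slide 1. The large peritoneal macrophage programme fell in 8 and rose in 0 of 11 (median −1.38, adjusted p 0.00367), with Vsig4 at least 51.2-fold and Prg4 at least 6.49-fold lower (a bound 1.86 times as large without PEC replicate 1). Above background on all 3 arrays were 10 of 18 listed members of this programme in PECs and 5 in F4/80low TAMs. Those kept by the filter on dim probes only through PECs were bound to fall. The peritoneal programme list had adjusted p = 0.290 with an estimated correlation and a median of −0.61 within slide 1. Cholesterol synthesis genes fell in 16 and rose in 0 of 19 (median −1.20, adjusted p 0.000217), with Dhcr7 (−3.10, SE 0.30), Mvd (−1.93, SE 0.36) and Msmo1 (−1.89, SE 0.38). The cholesterol list had adjusted p = 0.259 with an estimated correlation and a median of −1.36 within slide 1. Matrix remodelling genes fell in 11 and rose in 5 of 19 (median −2.03, adjusted p 0.0465), with Mmp12 (−8.65, SE 0.54; above background on 2 of 3 F4/80low arrays), the protease inhibitor Timp1 (−4.40, SE 0.50) and the plasminogen activator Plau (−3.33, SE 0.33). The matrix list had adjusted p = 0.259 with an estimated correlation and a median of −1.77 within slide 1. The matrix call was lost with normexp correction, with median centring, with slide as a block, within slide 1 and without PEC replicate 2 or PEC replicate 3. Leaving out 1 array moved Mmp12 to −8.05 (without F4/80low replicate 1), Timp1 to −5.02 (without PEC replicate 1) and Marco to −5.91 (without F4/80low replicate 3).

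The lists that did not pass the set test in F4/80low TAMs had 7 rising and 8 falling members of 17 for alternative activation, 4 and 8 of 17 for heme and iron handling, 4 and 4 of 15 for Nrf2 targets, 0 and 2 of 16 for glycolysis, 7 and 1 of 16 for hypoxia, 8 and 2 of 23 for oxidative phosphorylation, 6 and 4 of 14 for checkpoint genes and 3 and 0 of 7 for fibroblasts. Nrf2, hypoxia and oxidative phosphorylation passed with slide as a block. Hypoxia and oxidative phosphorylation also passed within slide 1. Oxidative phosphorylation passed as well with quantile normalization, with the percentile over spots above background on all arrays and without PEC replicate 3, and fibroblasts passed with median centring. In lists too small for the test the counts were 0 and 1 of 1 for B cells, 0 and 1 of 3 for endothelium, 1 and 0 of 1 for mesothelium, 1 and 0 of 1 for erythroid cells and 0 and 1 of 1 for platelets. Adjusted over the list alone, the counts differed for the peritoneal programme (1 and 8), alternative activation (8 and 8), oxidative phosphorylation (7 and 2), cholesterol (0 and 17), chemokines (12 and 5) and dendritic cells (5 and 1). Median and mean differed in sign for the endothelial list, and median, mean and test for the alternative activation list only before members are put at their bound.

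With slide as a block 4907 genes passed, and of 58 named genes 56 kept their side of the threshold, Mki67 (2.86) and Ccna2 (2.02) no longer passed, and Hmox1 changed sign. Msmo1 did not pass within slide 1. In the blocked fit the log2 fold change was 15.43 for S100a9, 10.05 for Plac8, 9.86 for Ccl5, 9.21 for Ccr7, 8.46 for Acod1, 7.47 for Tgtp2, 6.95 for Chil3, 6.52 for Mx1, 6.33 for Ifit3, 3.60 for Ccnb2, −3.15 for Timp1, −4.92 for Pmp22, −5.44 for Nes and −7.77 for Mmp12. The share of changed genes that were higher, 43.8%, moved to 22.1% with median centring and to 58.4% with the percentile over spots above background on all arrays.

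F4/80high TAMs, compared with F4/80low TAMs, carried more complement C1q, scavenger receptor, interferon and inflammatory transcript, and less neutrophil, T cell and NK cell transcript. C1qa, a chain of the complement initiator C1q, was 8.02 ± 0.46 in F4/80high and 3.30 ± 0.82 in F4/80low TAMs (log2 fold change 4.73, SE 0.42, adjusted p 8.22e-05). S100a8, the partner of S100a9, was 2.75 ± 1.65 in F4/80high and 9.21 ± 1.03 in F4/80low TAMs (log2 fold change −6.46, SE 0.77, adjusted p 0.000341; −7.20 without F4/80high replicate 1 and −5.57 without F4/80high replicate 2). Mertk was at least 23.0-fold higher in F4/80high TAMs, and Gzma at least 51.4-fold lower. In all, 5369 of 16463 genes passed the limma test, 3065 higher and 2304 lower in F4/80high TAMs.

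Further large rises in F4/80high TAMs were in P2ry6, a receptor for extracellular nucleotides (5.00, SE 0.35), the collagen gene Col14a1 (4.88, SE 0.45), the adhesion molecule Nectin2 (4.82, SE 0.25), the mannose receptor Mrc1 (4.72, SE 0.33) and C1qc (4.71, SE 0.40), with Plxdc2 at least 13.6-fold and Nxpe5 at least 11.7-fold higher. Further large falls were in the antimicrobial peptide gene Camp (−6.92, SE 1.66), Chil3 (−6.65, SE 0.96), the gelatinase Mmp9 (−6.53, SE 0.32), S100a9 (−6.30, SE 1.17) and the collagen-degrading cathepsin Ctsk (−6.28, SE 0.37), with Cstdc5 at least 64.7-fold and Chil1 at least 55.4-fold lower. F4/80low replicate 1 had the highest Camp, above 5.88 and 3.21 in the other two, and without it Camp stood at −4.94, Chil3 at −5.76, Cstdc5 at least 32.3-fold lower and Chil1 at least 31.5-fold lower. Camp stood at −8.58 without F4/80low replicate 3, −8.24 without F4/80high replicate 1, −6.30 without F4/80high replicate 2 and −6.22 without F4/80high replicate 3. S100a9 stood at −7.17 without F4/80high replicate 1 and −5.18 without F4/80high replicate 2, and Chil3 at −5.95 without F4/80high replicate 2.

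Interferon response genes were higher in F4/80high than in F4/80low TAMs in 22 and lower in 0 of 23 (median 2.60, adjusted p 3.60e-09), with Ifi44 (3.49, SE 0.68), Ifit2 (3.47, SE 0.50) and Ifit3 (3.23, SE 0.60). The interferon list had adjusted p = 0.337 with an estimated correlation. Without F4/80low replicate 1, Ifi44 stood at 2.53 and Ifit3 at 2.56. Inflammatory genes were higher in 12 and lower in 1 of 15 (median 2.55, adjusted p 9.77e-05), with Nos2 (3.65, SE 0.44), the cytokine Il6 (3.47, SE 0.33) and Socs3 (3.42, SE 0.35). The inflammatory list had adjusted p = 0.191 with an estimated correlation. Chemokines were higher in 14 and lower in 2 of 20 (median 1.99, adjusted p 6.91e-05), with Ccl12 (4.60, SE 0.37), Pf4 (4.08, SE 0.40) and Ccl7 (3.84, SE 0.44). The chemokine list had adjusted p = 0.239 with an estimated correlation. MHC class II genes were higher in 7 and lower in 1 of 10 (median 1.85, adjusted p 0.0130), with the peptide loader H2-DMa (2.97, SE 0.32) and H2-Aa (2.29, SE 0.31). The MHC class II list had adjusted p = 0.413 with an estimated correlation. Macrophage identity genes were higher in 7 and lower in 0 of 14, Adgre1 included (median 1.52, adjusted p 0.00526). The identity list had adjusted p = 0.337 with an estimated correlation. Phagocytic receptors were higher in 8 and lower in 2 of 16 (median 1.41, adjusted p 0.0303), with the scavenger receptors Stab1 (3.13, SE 0.31) and Msr1 (3.10, SE 0.25), and the call was lost without F4/80low replicate 3. The phagocytic list had adjusted p = 0.360 with an estimated correlation. Complement and lipid-associated genes were higher in 8 and lower in 2 of 17 (median 0.82, adjusted p 0.0401), with C1qb at 4.63 (SE 0.43), and the call was lost with median centring, with a replicate or slide block and without F4/80low replicate 1. The complement list had adjusted p = 0.454 with an estimated correlation.

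Neutrophil, T cell, NK cell, monocyte, and mast cell and eosinophil markers were lower in F4/80high than in F4/80low TAMs. Members kept by the filter on dim probes only through F4/80low TAMs were bound to go this way. Above background on all 3 F4/80high arrays were 2 of 10 listed NK and 4 of 12 T cell members, against 6 and 11 in F4/80low TAMs. Neutrophil markers were lower in 9 and higher in 0 of 12 (median −6.12, adjusted p 4.99e-06), with the granule gene Ngp (−7.65, SE 1.68) and Retnlg (−7.73, SE 1.03) above background on 1 and 2 of 3 F4/80high arrays. The neutrophil list had adjusted p = 0.337 with an estimated correlation. F4/80low replicate 1 had the highest Ngp, at 8.96 against 3.91 and 2.27, and without it Ngp stood at −5.70 and Retnlg at −6.90. Its removal moved the list median before members are put at their bound from −6.38 to −4.87. Without F4/80high replicate 1 the list median was −7.18, with Ngp at −9.04, Retnlg at −8.47 and Gzmb at −6.46. Without F4/80high replicate 2 it was −5.64, with Ngp at −6.88, Retnlg at −6.43 and Gzmb at −4.95. Ngp stood at −7.04 without F4/80high replicate 3 and −9.04 without F4/80low replicate 3. T cell markers were lower in 9 and higher in 0 of 11 (median −2.42, adjusted p 1.04e-07), with the adhesion receptor Cd2 at least 23.2-fold lower by its brightest probe and a second probe at −3.80 (SE 0.42), a smaller fold. The T cell list had adjusted p = 0.191 with an estimated correlation. NK cell markers were lower in 6 of 6 (median −2.78, adjusted p 1.72e-05), with Gzmb at −5.60 (SE 0.66; above background on 1 of 3 F4/80high arrays). The NK cell list had adjusted p = 0.191 with an estimated correlation. Monocyte markers were lower in 7 and higher in 0 of 10 (median −1.74, adjusted p 0.00036), with Plac8 at −5.73 (SE 0.74). The monocyte list had adjusted p = 0.191 with an estimated correlation. Mast cell and eosinophil markers were lower in 3 and higher in 0 of 5 (median −1.58, adjusted p 0.0130), with Kit at −2.08 (SE 0.30); Siglecf, above background on no F4/80high and 1 F4/80low array, gives no fold, its second probe stood at 0.19 (SE 0.21), and its call was lost with normexp correction, with the mean over probes, in the deposited value table and without F4/80high replicate 1 or F4/80high replicate 3. The mast cell list had adjusted p = 0.237 with an estimated correlation.

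Oxidative phosphorylation, cholesterol synthesis and Nrf2 target lists were lower in F4/80high than in F4/80low TAMs. Oxidative phosphorylation genes were lower in 18 and higher in 0 of 23 (median −0.65, adjusted p 1.33e-07), with Ndufa4 (−1.53, SE 0.19) and the succinate dehydrogenase genes Sdha (−1.14, SE 0.16) and Sdhb (−0.94, SE 0.18), the last not passing with median centring. The oxidative phosphorylation list had adjusted p = 0.337 with an estimated correlation. Cholesterol synthesis genes were lower in 10 and higher in 1 of 19 (median −0.79, adjusted p 5.74e-05), with Cyp51 (−2.65, SE 0.35) and Mvd (−2.07, SE 0.36), above background on 1 and 2 of 3 F4/80high arrays, and Msmo1 (−1.73, SE 0.38). The cholesterol list had adjusted p = 0.311 with an estimated correlation. Targets of Nrf2, the regulator of the oxidative stress response, were lower in 4 and higher in 0 of 15 (median −0.53, adjusted p 0.0303), a call lost in the fry test and with the percentile over spots above background on all arrays. The Nrf2 list had adjusted p = 0.454 with an estimated correlation. Among them were Osgin1 (−3.30, SE 0.42), the quinone reductase Nqo1 (−2.84, SE 0.83; above background on 2 of 3 F4/80high arrays) and Gclc of glutathione synthesis (−1.42, SE 0.35). Nqo1 stood at −3.47 without F4/80high replicate 3, and it did not pass without the filter on dim probes or without F4/80high replicate 1, F4/80high replicate 2, F4/80low replicate 2 or F4/80low replicate 3, and Gclc did not pass with median centring or without F4/80high replicate 2.

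The lists that did not pass between the subsets had 2 members higher and 1 lower in F4/80high of 11 for the peritoneal programme, 8 and 4 of 17 for alternative activation (adjusted p 0.0640), 3 and 2 of 17 for heme and iron handling, 2 and 1 of 16 for glycolysis, 2 and 4 of 16 for hypoxia, 11 and 3 of 19 for matrix remodelling, 7 and 2 of 14 for checkpoint genes (adjusted p 0.0523), 3 and 0 of 20 for the cell cycle (past the threshold without F4/80low replicate 1, median 0.80), 4 and 5 of 14 for dissociation, 1 and 2 of 7 for dendritic cells and 1 and 2 of 7 for fibroblasts. Matrix remodelling passed with slide as a block, with a replicate block on TAM arrays alone (median 1.08 in both) and with the percentile over spots above background on all arrays. Alternative activation passed with that percentile, with quantile normalization, with the mean over probes, without F4/80high replicate 3 and without F4/80low replicate 2. Checkpoint genes passed with that percentile, with normexp correction, with quantile normalization, with the mean over probes, with a replicate block on all or on TAM arrays, without the dim patch, and without F4/80high replicate 2, F4/80high replicate 3 or F4/80low replicate 2. In lists too small for the test the counts were 1 and 0 of 1 for B cells, 0 and 0 of 3 for endothelium, 0 and 1 of 1 for mesothelium, 0 and 1 of 1 for erythroid cells and 1 and 0 of 1 for platelets. Adjusted over the list alone, the counts differed for MHC class II (7 and 2), glycolysis (2 and 0), hypoxia (2 and 5), oxidative phosphorylation (0 and 19), cholesterol (1 and 11), matrix (12 and 3), chemokines (15 and 2), complement (9 and 3), cell cycle (2 and 0), phagocytic receptors (10 and 3) and T cells (0 and 10). Median, mean and test differed in sign for the peritoneal programme, heme, glycolysis and dendritic cell lists. With a replicate block 5187 genes passed, 4934 of them shared with the unpaired fit. The share of changed genes that were higher in F4/80high TAMs, 57.1%, moved to 75.9% with median centring and to 36.7% with the percentile over spots above background on all arrays.

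**Figure D3:**
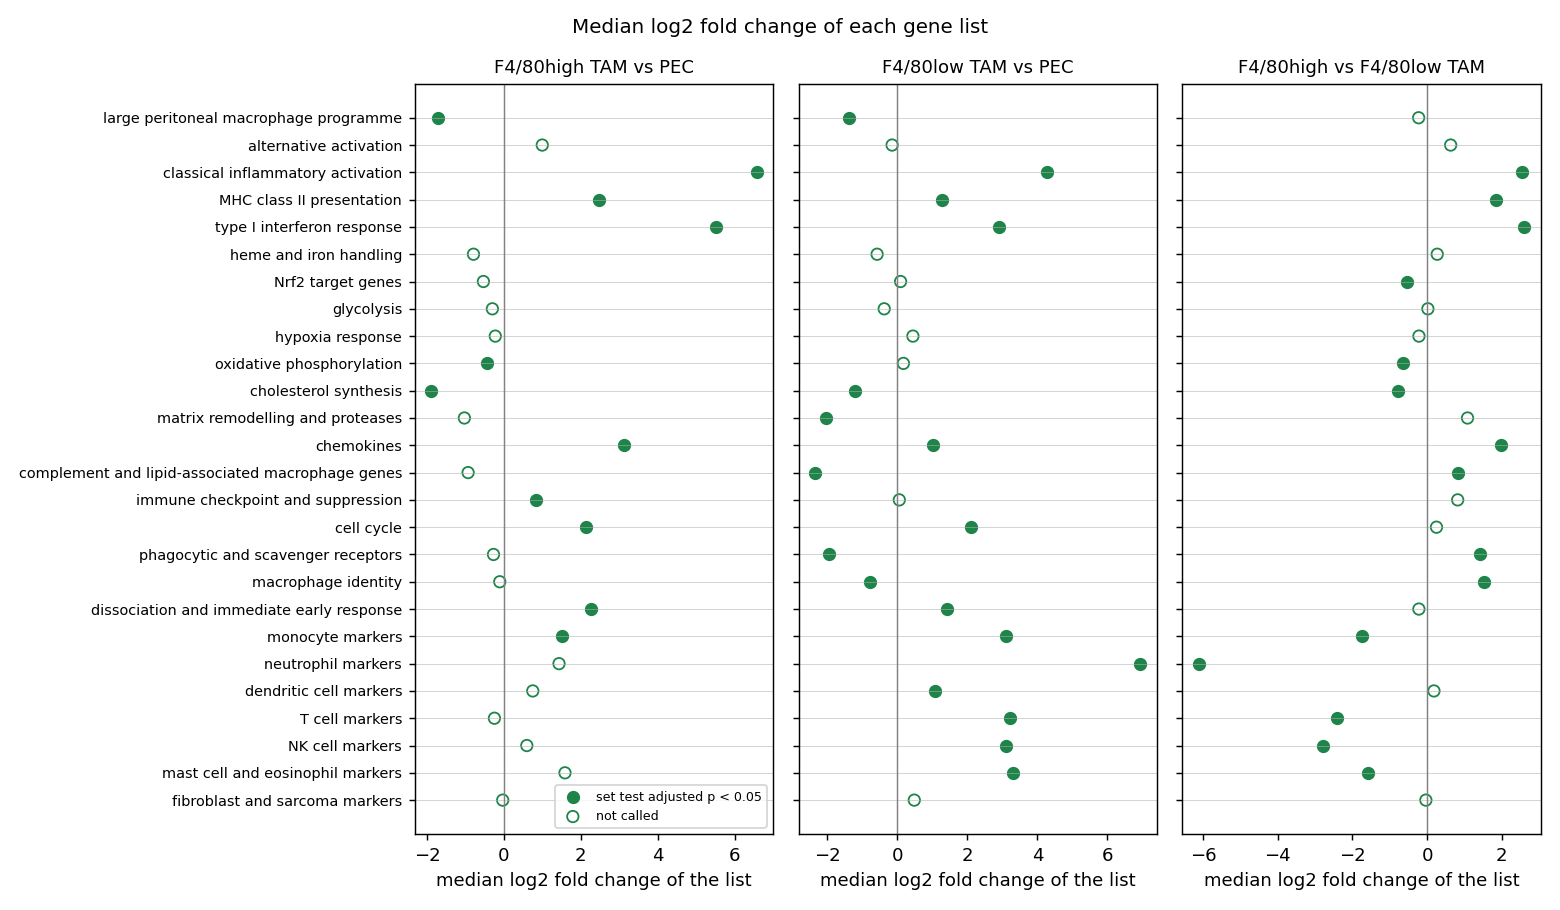
Median log2 fold change of each gene list in the 3 comparisons, with members not above background in one group entered at their bound; filled circles mark lists with a camera adjusted p under 0.05 and open circles the others, some of which, near 0, change sign with the scaling. Interferon response genes have medians of 5.52, 2.89 and 2.60 and neutrophil markers stand at 6.94 in F4/80low TAMs against PECs.

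Both TAM subsets shared a large part of their difference from PECs, with Ccl5, Gbp5, Acod1 and Ifit3 higher and Gpnmb, Lpl and Mmp12 lower in each. Of 16463 genes, 5771 passed in the same direction in both comparisons, 2529 higher and 3242 lower in both, where independent lists would share 936 and 1346. Simulations drew all 9 arrays, PECs included, without any difference between groups, so their 0 shared called genes followed from that setting. The fold changes correlated across genes, which are not independent replicates, at 0.74 against at most 0.53 in the simulations. The covariance was 1.82 against at most 0.0533. In the simulations the covariance came only from the spread of the shared PEC arrays, so spread of that size accounts for little of the observed covariance. A slide offset of PEC arrays was not drawn. Without real PEC arrays or group differences, the simulations cannot tell how many of the shared called genes come from the shared controls. The 3 PEC arrays were not divided between the comparisons, so part of the excess over independent lists may come from the shared controls. With slide as a block the overlap was 3079 genes. The split into higher and lower moved to 1324 and 3696 with median centring and to 2928 and 2739 with the percentile over spots above background on all arrays.

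C1qa, C1qb, C1qc and Ctsk moved in opposite directions in the TAM subsets. Against PECs, C1qa was 2.77 (SE 0.42) in F4/80high and −1.96 (SE 0.42) in F4/80low TAMs, C1qc 2.19 (SE 0.40) and −2.52 (SE 0.40), and C1qb 1.97 (SE 0.43) and −2.66 (SE 0.43), the C1qb rise not passing with slide as a block (1.57). Ctsk was 7.72 ± 0.22 in PECs, 4.16 ± 0.86 in F4/80high and 10.45 ± 0.18 in F4/80low TAMs, a log2 fold change of −3.56 (SE 0.37) and 2.73 (SE 0.37). Probes lie on chromosome 4 for C1qa (mm9, 136452409 to 136452468), C1qb (136436578 to 136436637) and C1qc (136445766 to 136445825), and on chromosome 3 for Ctsk (95313165 to 95313224). In all, 227 genes passed in opposite directions, 108 higher in F4/80high and lower in F4/80low TAMs and 119 the reverse. That 227 of these also passed between the subsets follows from the opposite directions.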

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

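The tests of a lower macrophage share, of dilution, of scaling and of a lower heme and Nrf2 response of a whole sample, and the use of regroupings that part every replicate pair, were chosen only after the result was seen.

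Against PECs, 227 genes passed in opposite directions in F4/80high and F4/80low TAMs. A difference between the subsets follows from such directions and is no further test. Among the named genes of this kind, the difference between F4/80high and F4/80low TAMs was 4.73 for C1qa, 4.71 for C1qc, 4.63 for C1qb and −6.28 for Ctsk.

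Neutrophil, T cell and NK cell transcripts were higher in F4/80low than in F4/80high TAMs, with S100a9 at 10.70 and S100a8 at 9.21 in F4/80low TAMs; without F4/80low replicate 1, the highest for Ngp (8.96 against 3.91 and 2.27), the median of neutrophil markers before members are put at their bound moved from −6.38 to −4.87. Whether a lower macrophage share raised all other cells alike cannot be told from the test made of it. With members at their bound, the 29 neutrophil, T and NK markers differed from 34 markers of all other cell types listed by −2.88. The means were −3.74 (SD 2.42) and −0.87 (SD 2.18), with p = 2e-05 in a two-sided permutation test. The neutrophil, T and NK lists were set apart after their values were seen, so a gap was largely built in. Genes of a list are also not independent, as that test takes them to be. Monocyte (mean −2.36) and mast cell and eosinophil markers (−1.24) moved the same way, the former by about as much as T cell markers (−2.53). Dendritic cell (−0.08) and fibroblast markers (−0.15) did so little. A second list of neutrophil genes, none of them on the earlier list, was lower in F4/80high TAMs in 13 of 18 measured members and higher in 0, with a median of −4.50 (−3.24 with members at their bound), while 6 of 18 were above background in PECs. A second list of T cell genes was lower in 8 of 10 and higher in 0 (median −3.72, −2.17 with members at their bound, 2 of 10 above background in PECs). In both second lists, members kept by the filter on dim probes only through F4/80low TAMs were bound to be higher there. Neutrophils and T cells among the sorted F4/80low cells are candidate sources. The labels name no marker of the gates besides F4/80, so whether such cells were gated out is not known. Immature myeloid cells that express neutrophil genes themselves stay open, untested, as does a change in gene expression of the F4/80low macrophages.

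Interferon response genes were higher in F4/80high than in F4/80low TAMs, with both subsets on the same slide. Scaling between arrays as the whole cause is argued against, since a factor common to an array cannot part these genes from the median of all genes, and with normexp correction and quantile normalization, which move genes unequally, their median lay 2.49 and 2.29 above it and the set passed in 2 of 2, though in the unaltered values it had adjusted p = 0.337 with an estimated correlation. Dilution of macrophage RNA by other cells in F4/80low samples cannot be told apart from a change within macrophages: interferon genes exceeded macrophage identity genes without Adgre1 by 0.926 (means 2.36, SD 0.79, n = 23, and 1.44, SD 1.83, n = 13; two-sided permutation test, p = 0.0390), but the identity genes spread widely, from Csf1r at −0.09 and Tyrobp at −0.13 to Lyz2 at 2.45. A biological difference in interferon signalling between the subsets stays open, untested here.

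Hmox1 was 4.16 in F4/80low replicate 2 against 7.94 and 8.94 in the other F4/80low arrays, a gap of −4.28 to their mean and the lowest of 14480 genes, and its second probe was lower by a gap of −1.64. Damage to that part of the array is argued against, since 38 bright spots around the Hmox1 spot differed from the other arrays by a median of 0.00527 (SD 0.45, lowest −0.65). A lower heme and Nrf2 response of the whole sample is argued against too, since the other 28 members of these lists differed by a median of 0.0918 (SD 0.46, lowest −0.51). The neighbouring spots do not bear on the Hmox1 spot alone, and the size of the drop differed between its probes. The main and second probe stood at 4.16 and 3.48 in replicate 2. They stood at 7.94 and 4.64 in replicate 1 and at 8.94 and 5.59 in replicate 3. Neither spot carried an outlier mark. The probes lie 280 rows apart, and 35 bright spots around the second one differed from the other arrays by a median of 0.0359 (SD 0.39). A defect of the main spot alone would not account for the lower second probe. Other explanations that concern single spots or probes were not tested. Other biological explanations were not tested either, as the labels divide the F4/80low samples no further.

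The 3 comparisons of groups have too few other splits of their arrays for a share under 0.05. For F4/80high TAMs against PECs the real split called 8737 genes and the highest of the others 0, and 1 of 10 splits, the real one, reached that count. For F4/80low TAMs against PECs the real split called 8541 and the highest other 0, again 1 of 10. For F4/80high against F4/80low TAMs the real split called 5369 and the highest other 0, which is 1 of the 4 splits that part every replicate pair, and the 6 other splits, which leave both arrays of at least 1 pair in the same group, called 0 too. For the overlap of both TAM subsets against PECs, 1 of 100 regroupings that part every replicate pair, the real one, gave as many as 5771 genes. The highest of the others gave 3093. Among 100 regroupings drawn without the limit on pairs, of which 52 part every pair, the real one alone reached its count. The highest other there gave 1417. None of the others in either draw kept the 3 PEC arrays together, so differences between PECs and TAMs entered their spread. Few shared genes were therefore likely beforehand, and the regroupings cannot tell whether chance or shared controls made the overlap. They also moved arrays across slides, and with slide as a block the overlap was 3079 genes.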

How the results depend on the processing

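Slide 1 alone, the percentile over spots above background on all arrays, the replicate block on TAM arrays alone and the removal of a dim patch were chosen only after the data were seen. No named gene or gene list with a call reversed under any alternative run. Of 3190 values of named genes under the alternatives, 3148 kept their side of the threshold, 41 lost the call and 1 gained it; of 1404 values of gene lists, 1286 kept their side, 72 lost the call and 46 gained one. Of those that kept their side, 12 values of named genes (Adgre1 in F4/80high and Hmox1 in F4/80low TAMs, each against PECs) and 44 list medians, over 16 lists and comparisons, changed sign, none of them past the threshold. In the order F4/80high against PECs, F4/80low against PECs, F4/80high against F4/80low and same direction in both, the counts of 8737, 8541, 5369 and 5771 genes became 5722, 5290, 3489 and 3371 with a fold minimum of 2, by construction. With slide as a block they became 5632, 4907, 5510 and 3079, and within slide 1 alone 4896 and 4127 for the PEC comparisons with 2584 shared, where a single PEC array carries each contrast. Without a filter on dim probes F4/80low against PECs gave 14388 genes, 9644 of them higher; the cause was not tested. Leaving out each array gave 7015 (without PEC replicate 3) to 8571 (without PEC replicate 1), 6602 (without PEC replicate 3) to 8468 (without PEC replicate 1), 3917 (without F4/80high replicate 2) to 4977 (without F4/80low replicate 3) and 4229 (without PEC replicate 3) to 5809 (without PEC replicate 1) genes. Of 44 calls of gene lists, 2 held with an estimated correlation, both for inflammatory activation against PECs. In each of these, 6 of 15 measured members were given as bounds, so the filter on dim probes partly set the call. The fry test made 57 calls, and leaving out arrays gave 41 to 45. The 9 arrays grouped by label in each alternative for which grouping was recomputed, and 8 of 8 did when an array was left out. Median centring moved the median of all genes by −0.16, −0.47 and 0.32, the percentile over spots above background on all arrays by −0.01, 0.24 and −0.25, and quantile normalization by −0.06, 0.06 and −0.11, in the order of the comparisons, so the share of higher genes moves with the scaling while the counts stayed within 1.5 times. A replicate block gave 8587, 8348, 5187 and 5625 genes, changed no named gene's call and, among lists, ended the complement call and began a checkpoint call between the subsets; PEC arrays did not pair with TAM arrays by number (residual correlations of −0.10 to 0.09). Signal over background limits the genes given as bounds, whose fold against a group at background is unknown above the bound.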

Other observations

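The genes in the biology paragraphs below, the dim patch and the listing of the value table were chosen or tested only after their values were seen.

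The heme and iron list did not pass between the TAM subsets, with 3 members higher and 2 lower in F4/80high of 17, and 4 members are given here as single values. Spic, a transcription factor of macrophages that recycle iron, was at 5.62 ± 0.45 in F4/80high and 4.91 ± 0.67 in F4/80low TAMs and above background on 1 of 3 PEC arrays; the subsets did not pass the test against each other (0.70, SE 0.45, adjusted p 0.276). Tfrc, the transferrin receptor that imports iron, was lower in F4/80high and higher in F4/80low TAMs than in PECs, at −3.07 (above background on 2 of 3 arrays) and 2.02 (difference between subsets −5.09, SE 0.19, adjusted p 1.85e-06). Slc40a1, the exporter ferroportin, was 3.38 higher in F4/80low TAMs than in PECs and −0.75 in F4/80high TAMs (adjusted p 0.0625), with a difference of −4.13 between subsets (SE 0.30). Cp, a ferroxidase that works with the exporter, was above background on all 3 F4/80high arrays, 2 F4/80low arrays and 0 PEC arrays, and 4.03 higher in F4/80high than in F4/80low TAMs (SE 0.33).

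Ifnb1, which encodes interferon beta, was at 5.73 ± 0.45 in F4/80high and 1.57 ± 0.38 in F4/80low TAMs and above background on 0 of 3 PEC arrays (difference between subsets 4.16, SE 0.27, adjusted p 1.54e-05). The alternative activation list did not pass between the subsets, with 8 members higher and 4 lower in F4/80high of 17: Mrc1 and Folr2, receptors of tissue macrophages, were higher in F4/80high than in F4/80low TAMs by 4.72 (SE 0.33) and 2.65 (SE 0.30), Chil3 was lower at −6.65 (SE 0.96; −5.95 without F4/80high replicate 2 and −5.76 without F4/80low replicate 1), and Arg1, which breaks down arginine, rose against PECs in both, by 3.17 and 2.90. The glycolysis list, with 2 higher and 1 lower of 16, did not pass, and its members Hk2 and Pfkfb3, which commit glucose to the pathway, were higher in F4/80high than in F4/80low TAMs by 1.64 (SE 0.30) and 2.67 (SE 0.32). The hypoxia list, with 2 higher and 4 lower of 16, did not pass. Its member Vegfa was lower in F4/80high than in F4/80low TAMs at −1.69 (SE 0.44), a call lost without F4/80high replicate 3 (−1.41) and without F4/80low replicate 2 (−1.45), and Ddit4 rose against PECs in both subsets, by 3.56 and 4.53.

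F4/80high replicate 3 held 85 spots more than 3 log2 units below the mean of the other F4/80high arrays. Of these, 69 lay in a patch within columns 1 to 6 that held 130 of 20609 bright spots. The software had marked 7 of the 85. Without the patch the counts of changed genes were 8771, 8605, 5389 and 5811, in the order F4/80high against PECs, F4/80low against PECs, F4/80high against F4/80low and same direction in both.

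The deposited value table lists probes of 7635 tested genes, of which 93.4% passed in at least 1 comparison, against 51.4% of the 8828 other tested genes.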
